A study of Mus musculus with 4 samples.

How the data were processed

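The deposited matrices held raw UMI counts per gene and cell barcode, with whole-number values that carried no normalization, per the file headers and the values themselves. They were made with Cell Ranger 5.0.0, per the file headers, and the labels list the builds mm10 and GRCh38 without saying what each was used for. The library kit was the 10x Genomics 3' v3.1 chemistry with feature barcodes, per the labels' protocols. Each deposited file listed 32285 genes with mouse Ensembl IDs and symbols, and 3 hashtag antibodies, whose counts were also deposited. The lowest total per deposited barcode was 500 UMIs, so barcodes had been filtered before deposit. How cells were told from empty droplets, and whether doublets were removed, is not given in the sources used here. Per the labels, 3 samples per condition were hashtagged and pooled, and there was 1 library per group. The labels do not say whether a hashtag number stood for the same cage, day or batch in different groups. Coordinates came from the GENCODE vM21 annotation of GRCm38, which held 32158 of the 32285 gene IDs (99.6%).

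Barcodes with at least 500 UMIs, at least 200 genes and under 15% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 8 cells (0.139%) of the Control library, so a common score of 0.25 was set after the data were seen, which removed 1.06% of Control, 2.48% of DAC, 9.38% of KBxN and 5.38% of DAC_KBxN cells. The 4 libraries were clustered together without integration, from counts per 10000 on a log scale, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, with seed 1. Clusters were named from markers chosen before the data were examined, by the mean scaled level of each class's markers, with at least 3 markers detected. A cluster stayed unnamed where its 10 leading genes held more markers of another class than of its own (clusters 4 and 16), where it had low UMIs and no marker of its own among them (cluster 42, led by interferon-stimulated genes, with 0, 0, 7 and 16 cells in Control, DAC, KBxN and DAC_KBxN), or where its score lay under a minimum set after the data were seen (cluster 35). Cluster 35 held 80, 88, 27 and 41 cells, or 1.40%, 1.01%, 0.156% and 0.315% of the libraries. Shares of cells were taken over all kept cells and without neutrophil-like and myeloid progenitor-like cells, with exact (Clopper-Pearson) intervals that cover counting error only. Fractions were compared with a two-sided exact permutation test over 20 arrangements. The names are rebuilt, and the study's own cell names were not used here.

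Hashtags were assigned with HTODemux of Seurat at its 0.99 quantile. Counts were summed per class and hashtagged fraction where every fraction of a group held at least 10 cells, and groups were compared where both libraries held at least 100. A library-level level is the class's count of a gene per 1000000 of the class's UMIs. Differences were tested with edgeR's quasi-likelihood test (robust) on 12 fractions in 1 fit per class, with filterByExpr, TMM factors and Benjamini-Hochberg adjustment over all genes tested. Osteoclast-like and monocyte-like cells were fitted on the KBxN and DAC_KBxN fractions alone. The contrasts were KBxN against Control, DAC_KBxN against KBxN, DAC against Control and the difference of the last 2. DAC_KBxN against KBxN and KBxN against Control share the KBxN library, so their overlap was not analysed here. Monocyte-like and macrophage-like cells were also summed together, as the plan was to test Irf8 there. The number of genes past the threshold in that sum is not reported. Tests were two-sided.

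The 20 gene lists and the rule for naming genes were fixed before the data were examined. The lists were osteoclast differentiation, osteoclastogenesis restraint, inflammatory cytokines and chemokines, interferon-stimulated, antigen presentation, resident macrophage, inflammatory macrophage, matrix degradation, RANKL and CSF1 axis, fibroblast activation, neutrophil granule, mature neutrophil, cell cycle, p53 targets, DNA methylation machinery, germline genes silenced by methylation, imprinted genes, dissociation stress, heat shock and chaperones, and glycolysis and hypoxia. Lists with at least 3 measured members were tested with limma's camera, with its preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the lists tested in that class and comparison. The germline list had too few measured members for this and is given as UMIs per library. Genes named are Irf8 in every class compared, 2 to 4 members with the most UMIs among those at least 1.5-fold apart in each list (or the most UMIs if none was), and up to 3 genes highest and 3 lowest by log2 fold change among those at adjusted p under 0.05, at least 50 UMIs and at least 2-fold apart, in neutrophil-like, monocyte-like, macrophage-like, fibroblast-like and endothelial-like cells. Some genes that this rule names are not reported here. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, Xist and Y-linked genes, unnamed models and other classes' markers were left out of that rule. A gene with 0 UMIs in a group is given as a lower bound against a floor of 3 counts over the group, and one with 1 to 3 UMIs as a ratio with its exact counting interval. A gene is called open to free RNA where its level in the class lay under 10% of that in other cells of the same libraries. Other genes can be free RNA too.

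The alternatives were a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), no cell filter, doublets kept, Leiden 0.5 and 2.0, cells thinned to 1000 UMIs, no TMM factors, totals without markers and the 50 most abundant genes, list members with at least 100 UMIs, DESeq2, no filter on low counts, an 80% hashtag rule and each fraction left out in turn. Further ones were chosen after seeing the data: fibroblast clusters with another class's marker put back, sums over all cells of the class without a test, barcodes with 2 hashtags removed, genes open to free RNA left out, and a 2-fold minimum beside adjusted p. A value was kept if its side of the threshold and, where called, its direction were the same, a count if within 1.5 times, and a share if its direction was the same.

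Before use, the fit was run on simulated counts with 200 genes changed. In macrophage-like cells for DAC_KBxN against KBxN, 76% of 2-fold and 94% of 4-fold changes were recovered among 8696 genes, and 6.59% of calls were false. In fibroblast-like cells for the same comparison the values were 89%, 97% and 3.63% among 12240 genes, and in macrophage-like cells for DAC against Control 65%, 95% and 4.19% among 6901 genes. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Seurat 5.3.0.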

Results

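Synovial cells from the paw and ankle joints of 8-week-old C57BL/6J mice were profiled by single-cell RNA sequencing with cell hashing, in which antibody-bound barcodes mark the sample a cell came from. The 4 groups were Control, DAC (decitabine, a nucleoside that inhibits DNA methyltransferases), KBxN (arthritis from transferred K/BxN serum, whose autoantibodies inflame the joints) and DAC_KBxN (both treatments). Each group was 1 pooled library of 3 hashtagged samples, and no group had a second library in the series. All titles read replicate 3, and other replicates were not used here. The tissue label said arthritic for all 4 groups, so the groups follow the titles and treatment labels. The libraries held 6335, 9674, 20155 and 14677 barcodes in that order, with 76135755, 99242343, 158690967 and 152966966 gene UMIs. Median UMIs per barcode were 10559 in Control, 8806.5 in DAC, 3923 in KBxN and 6495 in DAC_KBxN. After filtering, 5706, 8728, 17295 and 13030 cells were kept and named by fixed markers at the level of clusters.

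A hashtag was assigned to 33.1% of kept Control cells, 24.9% of DAC cells, 60.2% of KBxN cells and 38.9% of DAC_KBxN cells. Assignment reached 90.5% of macrophage-like and 96.3% of T cell-like cells but only 24.4% of fibroblast-like and 28.9% of endothelial-like cells. Values below are therefore given for whole libraries, with exact 95% intervals for shares, or for 3 hashtagged fractions per group. Log2 fold changes are followed by ± their standard error, and levels in counts per 1000000 UMIs (CPM) and shares by ± SD, with n = 3 fractions per group. Adjusted p-values are from edgeR. They measure the spread between fractions of 1 library, which may be technical, and not the spread between mice.

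The KBxN and Control libraries were compared to describe the arthritic joint. Neutrophil-like cells made up 25.7% (95% interval 25.1 to 26.4) of the KBxN library and 4.19% (95% interval 3.68 to 4.74) of the Control library. Monocyte-like cells rose from 0.351% (95% interval 0.214 to 0.541) to 9.24% (95% interval 8.81 to 9.68), and osteoclast-like cells from 0.105% (95% interval 0.0386 to 0.229) to 2.92% (95% interval 2.67 to 3.18). Macrophage-like cells were 10.0% (95% interval 9.57 to 10.5) in KBxN and 2.80% (95% interval 2.39 to 3.27) in Control. Dendritic cell-like cells were 5.87% (95% interval 5.52 to 6.23) and 1.77% (95% interval 1.44 to 2.15). Fibroblast-like cells took a smaller share, 29.7% (95% interval 29.1 to 30.4) against 44.6% (95% interval 43.3 to 45.9), and pericyte-like cells fell from 9.03% to 1.39%. Chondrocyte-like cells were 0.584% against 6.61% and endothelial-like cells 1.25% against 4.66%. Neutrophil-like cells were 37.0% ± 2.03 against 12.1% ± 1.46 of the hashtagged fractions, where the exact permutation p was 0.1, the smallest possible with 3 against 3. Without neutrophil-like and myeloid progenitor-like cells (marrow-type classes), macrophage-like cells were 13.7% against 3.00% and fibroblast-like cells 40.6% against 47.7%. Shares sum to 100% and depend on how well each cell type was released and captured.

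**Figure D1:**
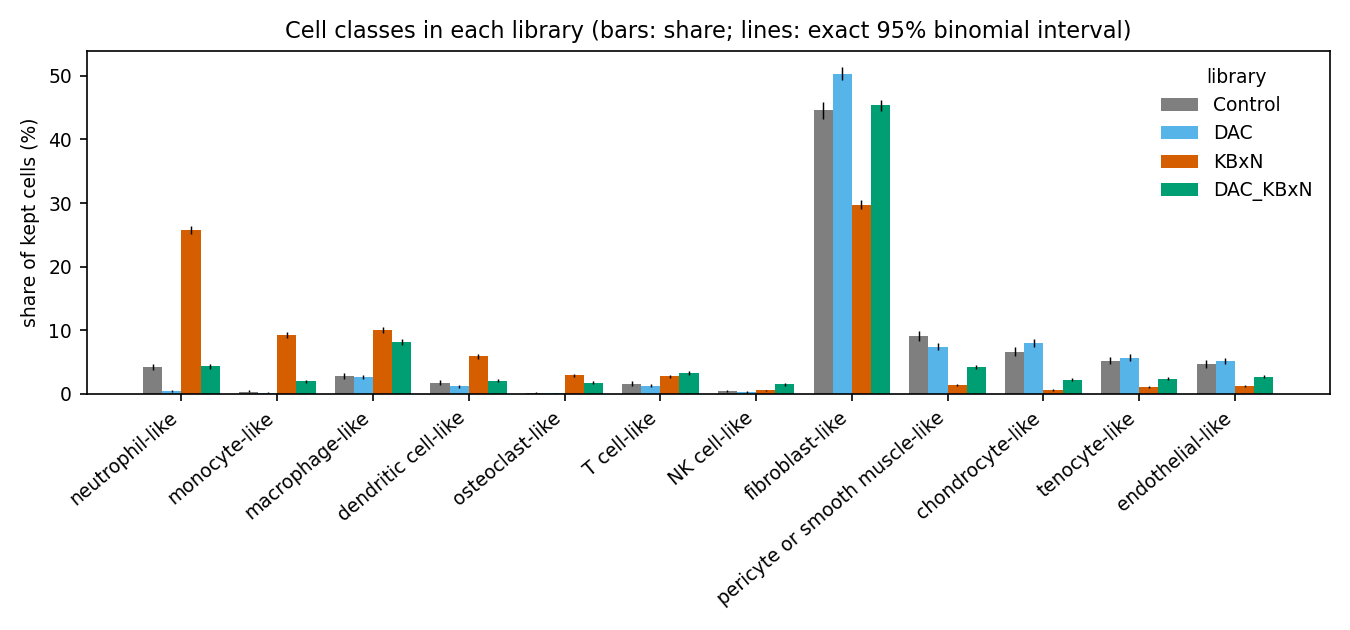
Bars give the percent of kept cells (vertical axis) in the larger cell classes of the Control, DAC, KBxN and DAC_KBxN libraries, and lines the exact 95% binomial intervals. Neutrophil-like cells stand at 25.7% in KBxN and 4.30% in DAC_KBxN.

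In macrophage-like cells of KBxN joints, Spp1 (osteopontin) rose by log2 6.04 ± 0.24 (5498 ± 313 CPM against 82.7 ± 7.77 CPM) and Thbs1 (thrombospondin 1) by 6.32 ± 0.35. Arg1 (arginase 1) was 367-fold (95% interval 126 to 1781) and Vegfa 251-fold (95% interval 85.8 to 1219) higher, while F7 (coagulation factor VII) was at least 22.4-fold and Nrg1 at least 17.9-fold higher, with 0 UMIs in Control. Among genes of resident macrophages, Lyve1 fell by -6.42 ± 0.24 (13.6 ± 7.32 CPM against 1152 ± 83.4 CPM), Folr2 by -2.34 ± 0.13 and Mrc1 by -1.18 ± 0.11. Ccl17 was lower by -7.18 ± 1.44, adjusted p = 0.00430, and Tppp was 87.5-fold (95% interval 29.1 to 432) lower. KBxN cells lay mainly in cluster 2, which Arg1 helped to define. Of Control cells 124 lay in cluster 29, 20 in cluster 2 and 16 in cluster 39, the last led by Ccl17, so these values hold a change of clusters. In all, 3336 of 8806 genes passed (1775 higher and 1561 lower) at adjusted p < 0.05.

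Of 11 inflammatory macrophage genes, 9 rose, 1 fell and 1 was not called (median 2.06, 9 higher and 1 lower when adjusted over the list alone, camera adjusted p = 1.3e-21, upward, 0.00305 with an estimated correlation). Among 12 resident macrophage genes, 0 rose, 9 fell and 3 were not called (median -1.74, 0 higher and 9 lower when adjusted over the list alone, camera adjusted p = 2.7e-16, downward, 0.00192 with an estimated correlation). All 9 glycolysis and hypoxia genes rose, Pgk1 by 2.45 and Ldha by 1.30 (median 1.99, camera adjusted p = 8.2e-21, upward, 0.00376 with an estimated correlation). For osteoclast differentiation, where Fosl2 rose by 1.74 and Acp5 by 1.70, of 9 genes 6 rose, 0 fell and 3 were not called (median 1.70, 6 higher and 0 lower when adjusted over the list alone, camera adjusted p = 1.4e-04, upward, 0.0323 with an estimated correlation). Interferon-stimulated genes such as Irf7 (3.32 ± 0.24) and Isg15 (1.44 ± 0.18) were also higher. Of 21 measured, 18 rose, 0 fell and 3 were not called (median 1.87, 19 higher and 0 lower when adjusted over the list alone, camera adjusted p = 8.9e-10, upward, adjusted p = 0.103 with an estimated correlation). With members at 0 counts set to their bound, that median was 1.83. Of 18 cell cycle genes 1 rose, 9 fell and 8 were not called (median -1.36, 1 higher and 10 lower when adjusted over the list alone, camera adjusted p = 0.0192, downward, adjusted p = 0.525 with an estimated correlation), with Stmn1 lower by -1.63 and Pcna higher by 0.65. The cell cycle median turned to 0.78 with no cell filter and 0.46 at Leiden 0.5. Cytokine and chemokine genes moved both ways, Ptgs2 by 4.09, Tnf by -1.84 and Ccl4 by -2.13. Of 15 measured, 7 rose, 4 fell and 4 were not called (median 0.58, 7 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.406, upward). In the DNA methylation machinery list Dnmt1 rose by 0.94 and Dnmt3a by 1.00, with no call for the list (median 0.20, camera adjusted p = 0.406).

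In fibroblast-like cells of KBxN joints, the neutrophil-attracting chemokine Cxcl5 rose by log2 10.78 ± 0.55 (1311 ± 73.0 CPM against 0.724 ± 0.0928 CPM). Ccl20 was at least 305-fold and Cxcl3 at least 202-fold higher, with 0 UMIs in Control, and Tnfsf11 (RANKL, the osteoclast growth signal) was 450.0-fold (95% interval 124 to 3719.7) higher. Mmp3 (stromelysin) rose by 3.87 ± 0.40, Timp1 by 4.09 ± 0.26 and the matrix protein gene Postn by 3.71 ± 0.19. Tnfrsf11b (osteoprotegerin, the decoy receptor of RANKL) fell by -1.52 ± 0.18 and Csf1 by -1.11 ± 0.05. Npy was lower by -6.36 ± 2.10 and Cldn3 by -5.75 ± 0.46, while Coch (-6.65) can be free RNA, as its level in this class was under 10% of that in other cells. Control cells lay mostly in clusters 1, 3, 5, 8, 18 and 20 and KBxN cells mostly in 6, 9, 10, 12 and 27. Cluster 10 was led by Cxcl5 and Tnfsf11 and 6 and 27 by cell cycle genes. In all, 8427 of 12599 genes passed (4241 higher and 4186 lower) at adjusted p < 0.05, 3345 of them at least 2-fold apart.

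Of 18 cytokine and chemokine genes in fibroblast-like cells, 17 rose, 0 fell and 1 was not called (median 3.55, 17 higher and 0 lower when adjusted over the list alone, camera adjusted p = 3.1e-10, upward, 0.0344 with an estimated correlation), Ccl2 by 2.13 and Ccl7 by 2.95. Among 12 fibroblast activation genes, 11 rose, 0 fell and 1 was not called (median 3.01, 12 higher and 0 lower when adjusted over the list alone, camera adjusted p = 7.6e-11, upward, 0.0478 with an estimated correlation), with Sfrp2 up by 5.07. All 18 cell cycle genes rose, Top2a by 4.41 (median 3.62, camera adjusted p = 2.5e-11, upward, 0.0478 with an estimated correlation), as did all 9 glycolysis and hypoxia genes, Pgk1 by 2.30 (median 1.38, camera adjusted p = 3.4e-09, upward, 0.0196 with an estimated correlation). For matrix degradation, of 9 genes 7 rose, 1 fell and 1 was not called (median 1.84, 7 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.0103, upward, adjusted p = 0.175 with an estimated correlation). In the RANKL and CSF1 list of 5 genes, 2 rose, 2 fell and 1 was not called, and the median (-0.78) and mean (1.36) had opposite signs (camera adjusted p = 0.807). The imprinted gene H19 rose by 5.82. Of 12 imprinted genes, 7 rose, 3 fell and 2 were not called (median 0.74, 7 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.00308, upward, adjusted p = 0.175 with an estimated correlation). Dissociation stress genes, induced during tissue digestion, were lower in KBxN. Of the 12 genes, 0 rose, 8 fell and 4 were not called (median -0.38, 0 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.00333, downward, adjusted p = 0.306 with an estimated correlation). For antigen presentation, H2-D1 fell by -1.63 and B2m by -0.86, and of 12 genes 9 rose, 3 fell and 0 were not called (median 1.04, 9 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.378, upward), with the higher Cd74 (4.84) open to free RNA.

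Neutrophil-like cells of KBxN joints carried more chemokine RNA, with Cxcl2 up by log2 1.89 ± 0.22 (17936 ± 664 CPM against 4841 ± 795 CPM) and Ccl4 by 2.69 ± 0.21. They carried less granule RNA, with Ngp down by -3.87 ± 0.69, Camp by -4.11 ± 0.88 and Ltf by -3.77 ± 0.75. Of 13 cytokine genes 12 rose, 0 fell and 1 was not called (median 2.45, 12 higher and 0 lower when adjusted over the list alone, camera adjusted p = 1.0e-11, upward, 0.0248 with an estimated correlation). All 8 neutrophil granule genes fell (median -3.32, camera adjusted p = 3.2e-08, downward, adjusted p = 0.102 with an estimated correlation). Of 10 mature neutrophil genes, 5 rose, 2 fell and 3 were not called (median 0.67, 5 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.150, upward). Control cells were split between clusters 0 and 32, the last led by granule genes, and KBxN cells lay mainly in cluster 0. Ldhc was lower by -4.59 and Tesc by -3.92. The higher Cthrc1 (at least 16.5-fold), Cxcl5 (at least 25.5-fold) and Ptx3 (at least 17.6-fold) can be free RNA of fibroblasts. In all, 1743 of 3928 genes passed (850 higher and 893 lower).

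Endothelial-like cells of KBxN joints, with 110, 86 and 21 in clusters 30, 28 and 25 (39, 96 and 131 in Control), had more of the proliferation genes Ube2c, 62.1-fold (95% interval 16.6 to 522), and Cenpe, 51.0-fold (95% interval 13.5 to 430.1), and of the apelin receptor Aplnr (log2 5.19 ± 0.90). Gdf10 was at least 19-fold lower and Penk lower by -5.65 ± 1.38, while Tnxb, 35.1-fold (95% interval 6.06 to 1413) lower, can be free RNA. Of 17 cell cycle genes 9 rose, 0 fell and 8 were not called (median 2.33, 14 higher and 0 lower when adjusted over the list alone, camera adjusted p = 1.1e-08, upward, adjusted p = 0.156 with an estimated correlation). Dissociation stress genes such as Fos (-1.91) and Junb (-1.49) were lower. Of the 12 members, 0 rose, 11 fell and 1 was not called (median -1.44, 0 higher and 12 lower when adjusted over the list alone, camera adjusted p = 3.6e-19, downward, 0.0153 with an estimated correlation). In all, 1223 of 6872 genes passed (600 higher and 623 lower) in endothelial-like and 1627 of 5987 genes passed (833 higher and 794 lower) in dendritic cell-like cells. Dendritic cell-like cells showed higher Vegfa (3.13 ± 0.32) and lower Cxcl10 (-2.46 ± 0.54). Of 13 interferon-stimulated genes, 7 rose, 2 fell and 4 were not called (median 1.54, 9 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.00698, upward, adjusted p = 0.242 with an estimated correlation).

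The series title names Irf8 (interferon regulatory factor 8, ENSMUSG00000041515, GRCm38 chromosome 8, 120736358 to 120756694, plus strand), a transcription factor of the monocyte lineage that restrains osteoclast formation. In pooled monocyte-like and macrophage-like cells its library level was 119 CPM (95% interval 104 to 135) in Control, 85.2 (73.2 to 98.6) in DAC, 104 (98.0 to 109.6) in KBxN and 140.5 (131 to 149.9) in DAC_KBxN. For KBxN against Control the log2 fold change was -0.07 ± 0.16, adjusted p = 0.768, which was not called. It was 0.22 ± 0.17, adjusted p = 0.325 in macrophage-like cells alone, also not called. Irf8 rose in dendritic cell-like cells by 1.04 ± 0.30, adjusted p = 0.0233 (265 ± 63.5 CPM against 127 ± 33.8 CPM). It also rose in hashtagged fibroblast-like cells by 1.48 ± 0.45, adjusted p = 0.00518, at a level that free RNA could supply. Over all fibroblast-like cells it was 2.25 CPM (95% interval 1.93 to 2.61) against 2.00 (1.58 to 2.50). It was not called in endothelial-like cells (1.05 ± 0.71, adjusted p = 0.324).

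**Figure D2:**
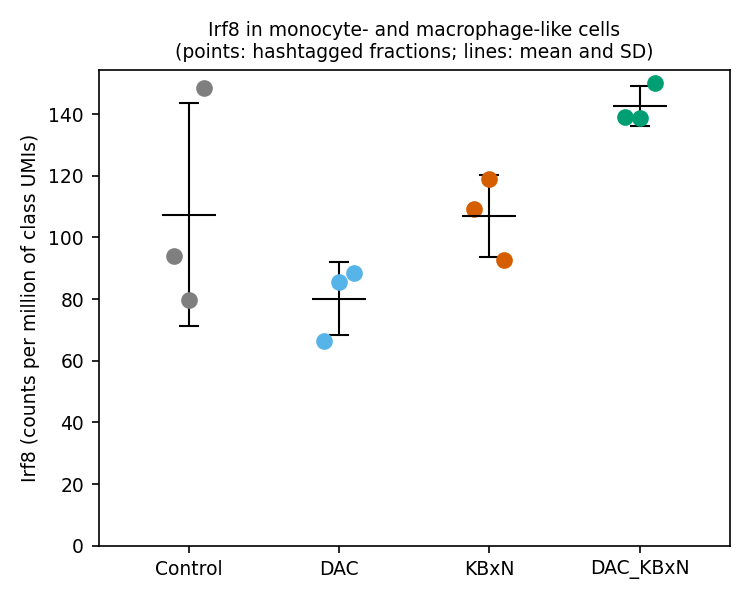
Irf8 in CPM (vertical axis) in pooled monocyte-like and macrophage-like cells, with 1 point per hashtagged fraction and the mean ± SD for each of the 4 groups. The 3 DAC_KBxN fractions lie between 139 and 150.1, above all 3 KBxN fractions, whose highest is 119.

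The DAC_KBxN and KBxN libraries were compared to ask what decitabine changed in arthritic joints. In DAC_KBxN, neutrophil-like cells were 4.30% (95% interval 3.96 to 4.66) of the library against 25.7% in KBxN. Monocyte-like cells were 1.94% (95% interval 1.71 to 2.19) against 9.24%, dendritic cell-like cells 2.04% (95% interval 1.81 to 2.30) against 5.87%, osteoclast-like cells 1.75% (95% interval 1.53 to 1.99) against 2.92% and myeloid progenitor-like cells 0.253% against 1.11%. Macrophage-like cells were 8.13% (95% interval 7.66 to 8.61) against 10.0% of the library but 18.8% ± 1.74 against 14.9% ± 0.748 of the hashtagged fractions, so their direction depended on the cells counted. Fibroblast-like cells were 45.4% (95% interval 44.5 to 46.2) against 29.7%, NK cell-like cells 1.49% against 0.526%, T cell-like cells 3.24% against 2.74% (3.39% against 3.75% without marrow-type classes, the opposite direction) and pericyte-like cells 4.23% against 1.39%. Neutrophil-like cells were 10.4% ± 1.05 against 37.0% ± 2.03 of the hashtagged fractions (exact permutation p = 0.1). Without marrow-type classes, monocyte-like cells were 2.03% against 12.6% and fibroblast-like cells 47.5% against 40.6%. Unnamed clusters held 14.2% of DAC_KBxN and 5.26% of KBxN cells, mostly in cluster 4, whose leading genes mixed fibroblast-like and chondrocyte-like markers.

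Irf8 rose in pooled monocyte-like and macrophage-like cells by log2 0.42 ± 0.12, adjusted p = 0.0166 (143 ± 6.47 CPM against 107 ± 13.3 CPM, from 807 and 1026 UMIs). In macrophage-like cells alone it was 0.23 ± 0.13, adjusted p = 0.288 and in monocyte-like cells alone 0.19 ± 0.18, adjusted p = 0.809, neither called. Macrophage-like cells gave 80.9% of the pooled UMIs in DAC_KBxN and 45.8% in KBxN, and with these shares held at their KBxN values the log2 ratio over fractions was 0.19 ± 0.17 (SD) in place of 0.48 ± 0.21. The call was lost with DESeq2 (0.41, adjusted p = 0.0934), with doublets kept (0.38, 0.113), with cells thinned to 1000 UMIs (0.37, 0.0917). It was also lost without DAC_KBxN fraction 3 (0.39, 0.0836), KBxN fraction 1 (0.44, 0.0523) or KBxN fraction 3 (0.33, 0.0848). Over all alternatives its adjusted p ran from 5.1e-05 to 0.113. Irf8 was not called in dendritic cell-like (0.40 ± 0.27, adjusted p = 0.604), osteoclast-like (0.21 ± 0.37, adjusted p = 0.761), fibroblast-like (0.43 ± 0.31, adjusted p = 0.307) or endothelial-like cells (0.69 ± 0.55, adjusted p = 0.696).

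Interferon-stimulated genes rose in most classes of DAC_KBxN joints. Irf7, a regulator of type I interferon genes, rose by log2 4.81 ± 0.18 in osteoclast-like cells (169.9 ± 21.2 CPM against 5.92 ± 2.31 CPM), 4.60 ± 0.53 in endothelial-like cells, 3.78 ± 0.12 in fibroblast-like cells (98.3 ± 3.80 CPM against 7.40 ± 2.40 CPM) and 1.77 ± 0.10 in macrophage-like cells (386 ± 7.23 CPM against 112 ± 16.0 CPM). Isg15, a ubiquitin-like interferon product, rose by 3.98 ± 0.18, 2.35 ± 0.41, 3.44 ± 0.26 and 1.02 ± 0.11 in these classes and by 2.72 ± 0.28 in T cell-like cells. Bst2 (tetherin, a virus-restricting membrane protein) rose by 2.84 ± 0.09 in fibroblast-like cells (431 ± 19.1 CPM against 60.2 ± 9.36 CPM), 2.06 ± 0.09 in osteoclast-like cells and 1.26 ± 0.09 in macrophage-like cells. The positions on GRCm38 are chromosome 7, 141262706 to 141266481 for Irf7 (ENSMUSG00000025498) and chromosome 4, 156199424 to 156200818 for Isg15 (ENSMUSG00000035692), both on the minus strand.

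**Figure D3:**
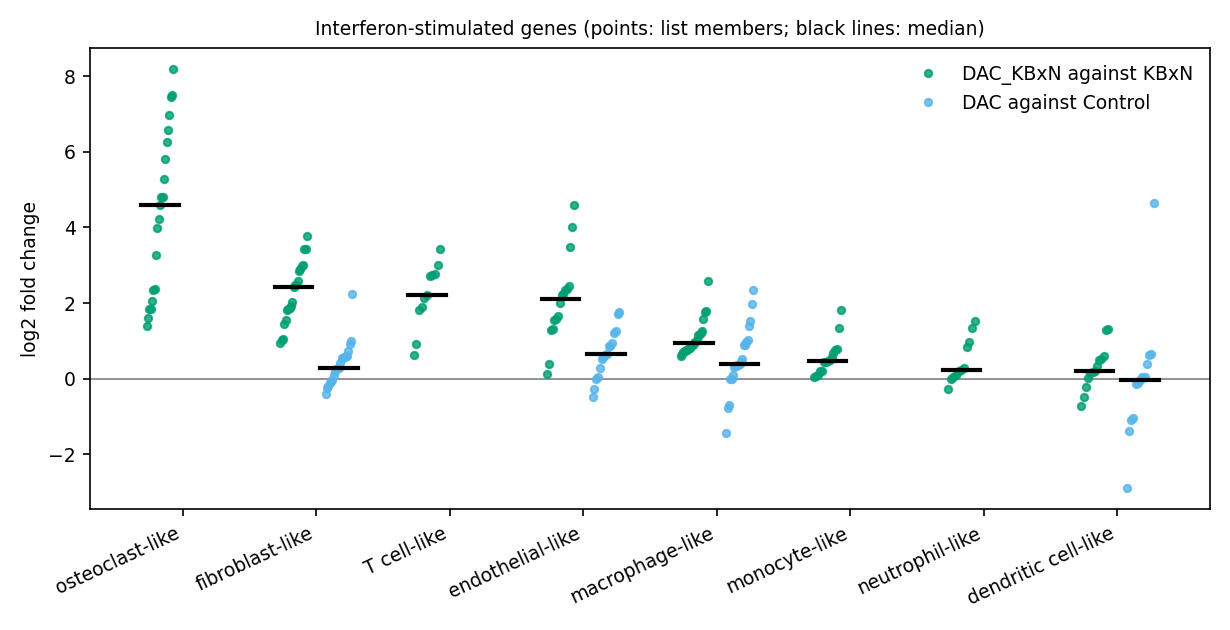
Log2 fold change (vertical axis) of each measured interferon-stimulated gene (points) by cell class, for DAC_KBxN against KBxN and, where fitted, DAC against Control, with black lines at the medians. For DAC_KBxN against KBxN the median is 4.59 in osteoclast-like, 2.41 in fibroblast-like and 0.94 in macrophage-like cells.

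Of 21 measured interferon-stimulated genes in osteoclast-like cells, 21 rose, 0 fell and 0 were not called (median 4.59, 21 higher and 0 lower when adjusted over the list alone, camera adjusted p = 4.2e-131, upward, 0.00778 with an estimated correlation). In fibroblast-like cells 20 rose, 0 fell and 1 was not called (median 2.41, 21 higher and 0 lower when adjusted over the list alone, camera adjusted p = 1.7e-47, upward, 0.00612 with an estimated correlation) of 21. The median within single fibroblast-like clusters ran from 0.29 in cluster 1 to 2.97 in cluster 12. Of the members 42.9% lay above their level in the other cells of the DAC_KBxN library. For T cell-like cells, of 11 genes 8 rose, 0 fell and 3 were not called (median 2.22, 11 higher and 0 lower when adjusted over the list alone, camera adjusted p = 2.8e-41, upward, 9.9e-04 with an estimated correlation). Endothelial-like cells measured 16, of which 6 rose, 0 fell and 10 were not called (median 2.11, 12 higher and 0 lower when adjusted over the list alone, camera adjusted p = 2.6e-28, upward, 0.00472 with an estimated correlation), with Ifit3 16.9-fold (95% interval 4.53 to 142) higher. Among 21 genes in macrophage-like cells, 17 rose, 0 fell and 4 were not called (median 0.94, 21 higher and 0 lower when adjusted over the list alone, camera adjusted p = 1.4e-30, upward, 0.00821 with an estimated correlation). Monocyte-like cells measured 15, of which 1 rose, 0 fell and 14 were not called (median 0.48, 3 higher and 0 lower when adjusted over the list alone, camera adjusted p = 3.7e-07, upward, adjusted p = 0.0910 with an estimated correlation). Neutrophil-like cells measured 11, of which 0 rose, 0 fell and 11 were not called (median 0.23, 3 higher and 0 lower when adjusted over the list alone, camera adjusted p = 4.7e-04, upward, adjusted p = 0.263 with an estimated correlation), with Irf7 at 0.84 ± 0.22, adjusted p = 0.0857. In dendritic cell-like cells 0 rose, 0 fell and 13 were not called (median 0.21, 1 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.131, upward) of 13. B2m, the light chain of class I molecules, rose by 1.73 ± 0.06 in fibroblast-like (991 against 298 CPM), 1.23 ± 0.17 in endothelial-like, 1.12 ± 0.05 in osteoclast-like and 1.03 ± 0.07 in macrophage-like cells.

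Macrophage-like cells of DAC_KBxN joints had less Spp1 (log2 -1.09 ± 0.17, 2588 ± 181 CPM against 5498 ± 313 CPM), Thbs1 (-1.52 ± 0.21), Vegfa (-1.25 ± 0.19) and Pgk1 (-1.02 ± 0.09), the last 2 of them responsive to low oxygen. Egln3, a hypoxia-induced prolyl hydroxylase, fell by -1.97 ± 0.23, and Ifitm1 by -2.17 ± 0.31. Trem2, a lipid receptor, rose by 0.89 ± 0.14, Folr2 by 1.35 ± 0.12, the chemokine gene Ccl8 by 2.40 ± 0.43 and Ly6a by 2.94 ± 0.28. Mamdc2 (ENSMUSG00000033207, GRCm38 chromosome 19, 23302609 to 23448442, minus strand) rose by 2.81 ± 0.37 (17.7 ± 2.55 CPM against 2.38 ± 0.516 CPM), and the interferon-induced GTPase gene Iigp1 by 2.94 ± 0.60. Arg1, which helped to define cluster 2, fell by -1.54 ± 0.33, adjusted p = 0.0155, and the lower Ptx3 (-2.01) can be free RNA. In all, 1233 of 8806 genes passed (650 higher and 583 lower) at adjusted p < 0.05, 159 higher and 90 lower by at least 2-fold.

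All 9 glycolysis and hypoxia genes fell in macrophage-like cells, Eno1 by -0.74 and Bnip3 by -1.23 (median -0.92, camera adjusted p = 8.5e-28, downward, 0.00170 with an estimated correlation). Of 11 inflammatory macrophage genes 1 rose, 6 fell and 4 were not called (median -0.88, 1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 1.1e-09, downward, 0.0102 with an estimated correlation). Resident macrophage genes shifted upward. Of the 12 genes, 2 rose, 0 fell and 10 were not called (median 0.46, 3 higher and 0 lower when adjusted over the list alone, camera adjusted p = 3.9e-04, upward, 0.0400 with an estimated correlation). For osteoclast differentiation, with Fosl2 at -0.86 ± 0.12, Nfatc1 at -0.59 ± 0.15 and Prdm1 at -0.83 ± 0.20, the list pointed downward. Of its 9 genes 0 rose, 3 fell and 6 were not called (median -0.36, 0 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.00293, downward, 0.0383 with an estimated correlation). Osteoclastogenesis restraint genes had no call for the list or any of 6 members (median -0.22, camera adjusted p = 0.183). Antigen presentation, of which 13 were measured, had 6 higher and 0 lower genes (median 0.42, camera adjusted p = 1.2e-09, upward, adjusted p = 0.0766 with an estimated correlation). Cytokine genes were mixed. Of the 15 members, 3 rose, 5 fell and 7 were not called (median -0.45, 3 higher and 6 lower when adjusted over the list alone, camera adjusted p = 0.0778, downward). No shift was called for cell cycle (median 0.05, camera adjusted p = 0.993), p53 target (median 0.02, 0.993), DNA methylation machinery (median -0.16, 0.859) or imprinted genes (median 0.25, 0.982). With monocyte-like cells added, the resident list had a median of 0.99 (camera adjusted p = 7.5e-07, upward, 0.0240 with an estimated correlation). Antigen presentation had -0.19 (camera adjusted p = 3.6e-04, upward, adjusted p = 0.313 with an estimated correlation). Both hold the shift in class shares of UMIs.

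Osteoclast-like cells of DAC_KBxN joints had more Ctsk (cathepsin K, log2 0.65 ± 0.04, 8868 ± 321 CPM against 5648 ± 117 CPM), Oscar (1.41 ± 0.18) and Itgb3 (0.69 ± 0.18), which serve bone resorption. The p53 target Cdkn1a rose by 0.88 ± 0.17 and Phlda3 by 1.62 ± 0.37. Of 13 osteoclast differentiation genes 8 rose, 0 fell and 5 were not called (median 0.36, 8 higher and 1 lower when adjusted over the list alone, camera adjusted p = 2.6e-06, upward, adjusted p = 0.315 with an estimated correlation). For antigen presentation, of 12 genes 7 rose, 2 fell and 3 were not called (median 0.74, 7 higher and 3 lower when adjusted over the list alone, camera adjusted p = 4.1e-11, upward, adjusted p = 0.226 with an estimated correlation). In all, 1228 of 8577 genes passed (769 higher and 459 lower), 239 higher and 24 lower by at least 2-fold. Clusters 21 and 36 held 198 and 30 of these cells against 395 and 110 in KBxN, so a change of clusters is part of these values. The Control and DAC libraries held 6 and 5 of them, too few for a fit.

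Fibroblast-like cells of DAC_KBxN joints had less Tnfsf11 (log2 -1.49 ± 0.20, 22.1 ± 6.96 CPM against 62.1 ± 8.67 CPM), Cxcl5 (-1.21 ± 0.24), Ccl7 (-0.98 ± 0.11) and Cxcl2 (-0.68 ± 0.15). Chaperone genes fell, Hspd1 by -0.81 ± 0.05 and Hsph1 by -0.88 ± 0.06, and the p53 targets Trp53inp1, Eda2r and Cdkn1a rose by 1.77 ± 0.14, 1.48 ± 0.28 and 0.72 ± 0.10. The largest increases were in interferon-responsive genes, Ifit3b at 4.49 ± 0.54, Cxcl9 at 4.36 ± 0.60 (71.5 ± 41.8 CPM against 3.51 ± 0.571 CPM) and Ccl5 at 4.16 ± 0.89. Tnc, an extracellular matrix gene, fell by -0.66, Adamts4 by -0.71 and Mest by -0.61, and Lrrc15 rose by 0.86. The lower Mcemp1 (39.9-fold (95% interval 10.7 to 336)), Il1f9 (-3.68) and Trem1 (-3.59) can be free RNA of neutrophils. Cxcl5 and Tnfsf11 helped to define cluster 10, and DAC_KBxN cells lay more in clusters 1, 3, 5 and 8 than KBxN cells did. In all, 4685 of 12599 genes passed (2496 higher and 2189 lower), 561 higher and 225 lower by at least 2-fold.

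Of 18 cytokine genes in fibroblast-like cells 1 rose, 11 fell and 6 were not called (median -0.66, 1 higher and 12 lower when adjusted over the list alone, camera adjusted p = 6.1e-08, downward, 0.0291 with an estimated correlation). All 7 heat shock and chaperone genes fell (median -0.59, camera adjusted p = 2.0e-11, downward, 0.00883 with an estimated correlation). For p53 targets, of 12 genes 8 rose, 1 fell and 3 were not called (median 0.44, 8 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0131, upward, adjusted p = 0.209 with an estimated correlation). Among 12 antigen presentation genes 6 rose, 4 fell and 2 were not called (median 0.32, 6 higher and 6 lower when adjusted over the list alone, camera adjusted p = 6.1e-05, upward, 0.0145 with an estimated correlation), with a mean of -0.15 and a median of -0.30 over all cells of the class. Cell cycle genes included Tyms (-0.68) and Hmgb2 (-0.62). Of the 18 members, 0 rose, 6 fell and 12 were not called (median -0.36, 0 higher and 6 lower when adjusted over the list alone, camera adjusted p = 0.00955, downward, adjusted p = 0.465 with an estimated correlation). For glycolysis and hypoxia, of 9 genes 1 rose, 6 fell and 2 were not called (median -0.34, 1 higher and 6 lower when adjusted over the list alone, camera adjusted p = 0.0106, downward, adjusted p = 0.126 with an estimated correlation). No shift was called for matrix degradation (median 0.03, camera adjusted p = 0.830), fibroblast activation (median -0.22, 0.188), the RANKL and CSF1 axis (median 0.31, camera downward, 0.755), DNA methylation machinery (median 0.03, 0.666), dissociation stress (median -0.09, 0.236) or imprinted genes (median 0.11, 0.760).

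Endothelial-like cells of DAC_KBxN joints had less Gja5 (connexin 40 of arterial endothelium, ENSMUSG00000057123, GRCm38 chromosome 3, 96904693 to 97077416, plus strand), by log2 -2.25 ± 0.37 (20.5 ± 6.42 CPM against 98.5 ± 14.2 CPM). Their clusters 30, 28 and 25 held 170, 95 and 85 cells against 110, 86 and 21 in KBxN, so these values hold a change of clusters. Hmmr, a mitotic gene, fell by -2.43 ± 0.58 and Fchsd2 by -1.38 ± 0.32, while Gbp2 rose by 2.25 ± 0.38 and Ccdc3 was 9.34-fold (95% interval 3.05 to 46.5) higher. Of 7 antigen presentation genes 5 rose, 0 fell and 2 were not called (median 1.34, 6 higher and 0 lower when adjusted over the list alone, camera adjusted p = 6.1e-15, upward, 0.00472 with an estimated correlation), H2-K1 by 1.5. Imprinted genes, Meg3 at 1.38 ± 0.64, adjusted p = 0.491 among them, had no gene called. Of the 9 members, 0 rose, 0 fell and 9 were not called (median 1.00, 2 higher and 0 lower when adjusted over the list alone, camera adjusted p = 2.2e-04, upward, 0.0208 with an estimated correlation). For p53 targets, of 10 genes 0 rose, 0 fell and 10 were not called (median 0.67, 3 higher and 0 lower when adjusted over the list alone, camera adjusted p = 1.0e-04, upward, adjusted p = 0.103 with an estimated correlation). In all, 58 of 6872 genes passed (46 higher and 12 lower), and 23 to 51 with 1 fraction left out.

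Monocyte-like cells of DAC_KBxN joints had more Cd36 (log2 1.87 ± 0.37), H2-Q7 (1.87 ± 0.35), Ly6a (1.69 ± 0.18) and Hk2 (0.93 ± 0.11), and less Cx3cr1 (-1.02 ± 0.18) and Hebp1 (-1.94 ± 0.48), with the lower Cxcl5 (-1.90) open to free RNA. Neutrophil-like cells had more Ifi207 (1.61 ± 0.28, adjusted p = 0.00336) and less Egr1 (-0.64 ± 0.14, adjusted p = 0.0247). Their higher Cavin1 (1.5 ± 0.34, adjusted p = 0.0479) and lower Cxcl5 (-1.76) and H2-Ab1 (-1.34) can be free RNA. Their granule (median -0.04, camera adjusted p = 0.998) and mature neutrophil lists (median -0.07, 0.522) had no call. Of 12 dissociation stress genes, 0 rose, 1 fell and 11 were not called (median -0.24, 0 higher and 4 lower when adjusted over the list alone, camera adjusted p = 4.7e-04, downward, adjusted p = 0.193 with an estimated correlation). In T cell-like cells Bst2 rose by 2.22 ± 0.31, adjusted p = 0.00147. B2m rose by 0.60 ± 0.10, adjusted p = 5.5e-04 in dendritic cell-like cells. In all, 51 of 7058 genes passed (43 higher and 8 lower) in monocyte-like and 13 of 3928 genes passed (5 higher and 8 lower) in neutrophil-like cells. Likewise 113 of 5987 genes passed (84 higher and 29 lower) in dendritic cell-like and 37 of 4799 genes passed (30 higher and 7 lower) in T cell-like cells. With 1 fraction left out these counts ran from 22 to 126, 3 to 24, 29 to 108 and 12 to 20 in that order.

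The DAC and Control libraries were compared to ask what decitabine did without arthritis. Neutrophil-like cells were 0.367% (95% interval 0.251 to 0.517) of the DAC library against 4.19% of Control, from 32 and 239 cells, and myeloid progenitor-like cells 0.309% (95% interval 0.204 to 0.45) against 2.28%. B cell-like cells were 0.561% against 1.52%, macrophage-like cells 2.67% (95% interval 2.34 to 3.03) against 2.80% and fibroblast-like cells 50.3% (95% interval 49.3 to 51.4) against 44.6%. In macrophage-like cells Irf7 rose by log2 1.54 ± 0.33, adjusted p = 0.0143 (32.7 ± 3.13 CPM against 12.3 ± 6.41 CPM), Ang (angiogenin) by 1.13 ± 0.20, adjusted p = 0.00362 and Lgals3bp by 1.08 ± 0.24, adjusted p = 0.0232. The mitotic genes Spc25 (-2.82 ± 0.53), Ndc80 (-2.50 ± 0.58) and Prc1 (-2.46 ± 0.43) fell. In fibroblast-like cells Ripor3 (1.27 ± 0.33), the pyruvate dehydrogenase kinase gene Pdk4 (1.05 ± 0.26), Ptges3l (1.05 ± 0.21) and Adamts4 (0.70 ± 0.18) rose. Pcdhb20 (-1.76 ± 0.40) and Gfod2 (-1.17 ± 0.29) fell, while the lower Slc7a11 (-3.52) can be free RNA. Genes past adjusted p < 0.05 numbered 53 of 8806 in macrophage-like, 202 of 12599 in fibroblast-like, 3 of 5987 in dendritic cell-like and 0 of 6872 in endothelial-like cells. The macrophage-like count was 237 without Control fraction 1 and 18 without Control fraction 3, and the fibroblast-like count 111 without DAC fraction 2. In endothelial-like cells edgeR gave 528 genes at unadjusted p < 0.05 and DESeq2 called 13.

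Irf8 was not called in any class of this comparison, with -0.48 ± 0.21, adjusted p = 0.359 in pooled monocyte-like and macrophage-like cells (80.1 ± 11.9 CPM against 107 ± 36.2 CPM). It stood at -0.51 ± 0.20, adjusted p = 0.311 in macrophage-like and -0.29 ± 0.35, adjusted p = 0.921 in dendritic cell-like cells. In the stroma it was 0.64 ± 0.51, adjusted p = 0.650 in fibroblast-like and 1.18 ± 0.61, adjusted p = 0.686 in endothelial-like cells. Of 21 interferon-stimulated genes in macrophage-like cells 1 rose, 0 fell and 20 were not called (median 0.40, 3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00345, upward, adjusted p = 0.424 with an estimated correlation). With members of at least 100 UMIs that direction turned (median -0.77). In fibroblast-like cells 0 rose, 0 fell and 21 were not called (median 0.28, 0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00176, upward, adjusted p = 0.411 with an estimated correlation) of 21, a call lost under the 80% hashtag rule (median -0.0199). Endothelial-like cells measured 16, of which 0 rose, 0 fell and 16 were not called (median 0.64, 0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00185, upward, adjusted p = 0.529 with an estimated correlation). For cell cycle in macrophage-like cells, of 18 genes 0 rose, 1 fell and 17 were not called (median -1.30, 0 higher and 7 lower when adjusted over the list alone, camera adjusted p = 3.2e-16, downward, adjusted p = 0.309 with an estimated correlation). Antigen presentation genes in these cells, H2-Ab1 at -1.12 among them, pointed downward. Of the 13 members, 0 rose, 0 fell and 13 were not called (median -0.62, 1 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.00345, downward, adjusted p = 0.424 with an estimated correlation). That direction turned with no cell filter (median 0.22) and at Leiden 0.5 (0.03). Among 12 imprinted genes in fibroblast-like cells 0 rose, 0 fell and 12 were not called (median -0.23, 0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00314, downward, adjusted p = 0.411 with an estimated correlation). The DNA methylation machinery list had no call (median -0.11, camera adjusted p = 0.241). The 16 germline genes known to be silenced by methylation, Dppa3 among them, gave 75 UMIs in Control, 82 in DAC, 369 in KBxN and 263 in DAC_KBxN over whole libraries. That was 1.01 (95% interval 0.796 to 1.27), 0.872 (0.693 to 1.08), 2.75 (2.47 to 3.04) and 1.86 (1.64 to 2.10) CPM. Dppa3 alone gave 29, 26, 275 and 160 of these UMIs, so the higher KBxN and DAC_KBxN values rest mostly on this gene.

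The effect of decitabine with arthritis was then compared with its effect without. It was larger by log2 0.89 ± 0.24 (adjusted p = 0.0322) for Irf8 in pooled monocyte-like and macrophage-like cells, a call kept in 10 of 23 alternatives (range 0.48 to 1.07). For Mamdc2 in macrophage-like cells it was larger by 2.79 ± 0.44 (adjusted p = 1.4e-04). In endothelial-like cells it differed for Irf7 (4.33 ± 0.79, adjusted p = 0.0206) and Gja5 (-3.18 ± 0.50, adjusted p = 0.00537). Interferon-stimulated genes responded more with arthritis, by a median of 1.69 in fibroblast-like cells (camera adjusted p = 3.2e-14, upward, adjusted p = 0.0575 with an estimated correlation). The median was 1.18 in endothelial-like (camera adjusted p = 3.2e-07, upward, 0.132 with an estimated correlation) and 0.41 in macrophage-like cells (0.00507 and 0.405). Genes past adjusted p < 0.05 numbered 2654 in fibroblast-like (1668 higher and 986 lower), 274 in macrophage-like (168 and 106), 21 in dendritic cell-like and 21 in endothelial-like cells (9 to 44 and 2 to 28 in the last 2 with 1 fraction left out).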

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

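The results of this part stand out because the effect of decitabine with arthritis differed from its effect without, by a test of the difference. The tests of a class shift, of shifts between fibroblast-like clusters and of what the hashtags mark were chosen after the result was seen, and those of library differences, free RNA and split fractions before. For Irf8 in pooled monocyte-like and macrophage-like cells the difference was log2 0.89 ± 0.24 (adjusted p = 0.0322, from 1.6e-04 to 0.818 over the alternatives). A shift from monocyte-like to macrophage-like cells could raise the pooled level. With class shares of UMIs held at KBxN values the ratio of DAC_KBxN to KBxN fell from log2 0.48 to 0.19 (SD 0.17 over fractions). This is too near its SD to decide, and DAC against Control was not covered. A difference between the 2 libraries other than the drug cannot be told apart from an effect of the drug, since the number of libraries per group was 1.

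Interferon-stimulated genes had a higher effect of decitabine with arthritis at camera's preset correlation, by a median of log2 1.69 in fibroblast-like cells (camera adjusted p = 3.2e-14, adjusted p = 0.0575 with an estimated correlation), 1.18 in endothelial-like cells (3.2e-07 and 0.132), 0.64 in pooled monocyte-like and macrophage-like cells (9.4e-05 and 0.301) and 0.41 in macrophage-like cells (0.00507 and 0.405), so all 4 calls were lost with an estimated correlation. Free RNA taken up by droplets was excluded as the whole cause in osteoclast-like cells, where 81.0% of the measured members stood above their level in all other cells of the DAC_KBxN library. The same bar, at least 50%, was passed in T cell-like (81.8%), endothelial-like (93.8%), macrophage-like (95.2%) and neutrophil-like cells (72.7%, no gene called). Fibroblast-like (42.9%) and monocyte-like cells (46.7%) fell short. The bar is on the level, not the rise, so for these smaller rises free RNA was not excluded. A shift between fibroblast-like clusters cannot raise levels inside a cluster. The lowest median (DAC_KBxN against KBxN) was 1.55 in clusters 6, 9, 10, 12 and 27, arguing against a shift as the whole cause there. It was 0.29 in clusters 1, 3, 5 and 8, too low to decide. Sets were formed from these values, and the shift's part in the class median was not tested. A difference between the 2 libraries other than the drug, such as an infection or handling, cannot be told apart from the drug with 1 library per group, so that decitabine raises these genes in arthritic joints is a hypothesis.

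The hashtagged fractions of a library may be parts of 1 cell suspension rather than separate mice. The median ratio of the spread between fractions to that of random splits was 0.986, which fits that explanation, and 0 of 28 tests lay above all 50 random splits. The lowest chi-square p for class counts by fraction was 0.0035 (KBxN), and on the make-up of the cells the explanation cannot be told apart from separate samples. No biological explanation was tested.

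Mamdc2 in macrophage-like cells stood out by a difference of log2 2.79 ± 0.44 (adjusted p = 1.4e-04) between the drug effects. Irf7 in endothelial-like cells differed by log2 4.33 ± 0.79 (adjusted p = 0.0206). Gja5 in endothelial-like cells differed by log2 -3.18 ± 0.50 (adjusted p = 0.00537).

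The fractions were also regrouped at random and the genes past the threshold counted again. For the difference of drug effects, 1 of 50 splits, the real one, reached 2654 genes in fibroblast-like cells (highest other 36). In macrophage-like cells 1 of 50 reached 274 (highest other 123). Other splits mixed fractions of different libraries, while the real one kept each library whole. Any difference between libraries, arthritis included, would favour the real split, so this cannot test the difference of drug effects. The other comparisons had 10 splits each, with the same limit and too few to exclude random grouping. For KBxN against Control 1 of 10 reached the real count, with 0 in the highest other split, for neutrophil-like (1743), macrophage-like (3336), dendritic cell-like (1627), fibroblast-like (8427) and endothelial-like cells (1223). For DAC_KBxN against KBxN it was also 1 of 10 in neutrophil-like (13), monocyte-like (51), macrophage-like (1233), dendritic cell-like (113), osteoclast-like (1228) and fibroblast-like cells (4685), where the highest other was 0, and in T cell-like (37) and endothelial-like cells (58), where it was 1. For DAC against Control it was 1 of 10 in fibroblast-like cells (202, highest other 4), 2 of 10 in macrophage-like cells (53, highest other 65), 5 of 10 in dendritic cell-like cells (3, highest other 47) and 10 of 10 in endothelial-like cells (0, highest other 1).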

How the results depend on the processing

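Below, the model is KBxN against Control, the treated model DAC_KBxN against KBxN, the drug alone DAC against Control, the interaction the difference of the drug effects, and pooled means monocyte-like with macrophage-like cells. Interferon genes are the interferon-stimulated list, and bare counts are genes past the threshold. Most alternatives were fixed before the data were examined, and the 2-fold minimum, fibroblast clusters put back and sums over all cells of the class were chosen after seeing the data. The last has no test. Each value stands before its main value, list values are medians of log2 fold changes, and the direction of a list is that of camera, which can differ from the sign of its median. Kept in every tested alternative were the interferon gene calls in the treated model in macrophage (0.80 to 1.26), pooled (1.17 to 1.39), osteoclast (3.80 to 5.25), fibroblast (1.85 to 2.55) and endothelial cells (1.78 to 2.29), untested sums included in the ranges. Over all alternatives 266 counts were kept and 101 moved past 1.5 times. Irf8 calls held in 13 of 19 (treated model) and 10 of 23 (interaction). Of named genes 1254 results were kept, 157 lost their call, 12 gained one, 30 moved and 0 turned. The neutrophil share difference ran from -21.4 to -9.91 points in the treated model and from 8.52 to 21.6 in the model. By a rule fixed before the data, no block was fitted, as no label ties hashtag numbers to a batch. Monocyte-like cells were not named at Leiden 0.5, so not run there. Fibroblast-like and endothelial-like cells rest on the smaller part that carried a hashtag, and depth limits low genes, since KBxN had the lowest median UMIs. The cause of each change below was not tested, except that the 2-fold minimum lowers counts by construction. A left-out fraction, named by group and number, leaves 2 in its group. Thinning gave 616 for 1743 in neutrophil, 807 for 3336 in macrophage, 246 for 1627 in dendritic, 1784 for 8427 in fibroblast and 75 for 1223 in endothelial cells (model). Thinning gave 40 for 13 in neutrophil, 18 for 51 in monocyte, 540 for 1233 in macrophage, 60 for 113 in dendritic, 120 for 1228 in osteoclast, 788 for 4685 in fibroblast and 9 for 58 in endothelial cells (treated model). Thinning gave 3 for 53 in macrophage, 1 for 3 in dendritic, 23 for 202 in fibroblast and 3 for 0 in endothelial cells (drug alone). Thinning gave 39 for 274 in macrophage and 300 for 2654 in fibroblast cells (interaction). Thinning lost the call of Irf8 (pooled, treated model, 0.37 for 0.42), Irf8 (pooled, interaction, 0.48 for 0.89) and interferon genes (macrophage, drug alone, 0.95 for 0.40). Thinning lost the call of interferon genes (pooled, model, 1.03 for 1.62), interferon genes (fibroblast, drug alone, 0.48 for 0.28) and osteoclast differentiation genes (pooled, model, 0.20 for 1.5). Thinning turned the direction of antigen presentation genes (neutrophil, treated model, 0.24 for 0.0792), cytokine genes (pooled, model, -0.86 for 0.88) and interferon genes (pooled, drug alone, -0.41 for 0.43). Thinning gained the call of antigen presentation genes (pooled, model, 0.29 for 0.28). The 2-fold minimum gave 864 for 1743 in neutrophil, 1536 for 3336 in macrophage, 822 for 1627 in dendritic, 3345 for 8427 in fibroblast and 796 for 1223 in endothelial cells (model). The 2-fold minimum gave 5 for 13 in neutrophil, 11 for 51 in monocyte, 249 for 1233 in macrophage, 56 for 113 in dendritic, 263 for 1228 in osteoclast and 786 for 4685 in fibroblast cells (treated model). The 2-fold minimum gave 23 for 53 in macrophage and 13 for 202 in fibroblast cells (drug alone). No count filter gave 58 for 13 in neutrophil, 226 for 113 in dendritic, 65 for 37 in T and 182 for 58 in endothelial cells (treated model). No count filter gave 210 for 53 in macrophage, 22 for 3 in dendritic, 417 for 202 in fibroblast and 33 for 0 in endothelial cells (drug alone). No count filter gave 432 for 274 in macrophage cells (interaction). No count filter gained the call of antigen presentation genes (pooled, model, 0.37 for 0.28) and interferon genes (fibroblast, model, 1.07 for 1.03). No cell filter gave 116 for 51 in monocyte and 23 for 37 in T cells (treated model), 12 for 53 in macrophage and 7 for 3 in dendritic cells (drug alone). No cell filter lost the call of Irf8 (pooled, interaction, 0.57 for 0.89). No cell filter turned the direction of cell cycle genes (macrophage, model, 0.78 for -1.36), cell cycle genes (pooled, model, 0.35 for -1.95) and antigen presentation genes (macrophage, drug alone, 0.22 for -0.62). No cell filter turned the direction of antigen presentation genes (pooled, drug alone, 0.0600 for -0.54). No cell filter gained the call of antigen presentation genes (pooled, model, 1.5 for 0.28). No cell filter turned the osteoclast share difference, drug alone, from -0.0479 to 0.0265 points. The stricter filter gave 7 for 51 in monocyte and 100 for 37 in T cells (treated model), 10 for 53 in macrophage cells (drug alone), 413 for 274 in macrophage cells (interaction). The stricter filter turned the direction of granule genes (neutrophil, treated model, -0.43 for -0.0408) and interferon genes (pooled, drug alone, -0.12 for 0.43). The stricter filter gained the call of antigen presentation genes (pooled, model, 0.99 for 0.28) and interferon genes (fibroblast, model, 1.28 for 1.03). The stricter filter lost the call of antigen presentation genes (pooled, drug alone, -0.13 for -0.54). The stricter filter turned the T cell share difference, treated model, from 0.498 to -0.294 points. Leiden 0.5 gave 2416 for 1233 in macrophage cells (treated model), 13 for 53 in macrophage cells (drug alone), 501 for 274 in macrophage cells (interaction). Leiden 0.5 lost the call of Irf8 (pooled, interaction, 0.59 for 0.89). Leiden 0.5 turned the direction of cell cycle genes (macrophage, model, 0.46 for -1.36), cell cycle genes (pooled, model, 0.46 for -1.95) and antigen presentation genes (macrophage, drug alone, 0.0343 for -0.62). Leiden 0.5 turned the direction of antigen presentation genes (pooled, drug alone, 0.0343 for -0.54). Leiden 0.5 gained the call of antigen presentation genes (pooled, model, 1.47 for 0.28). DESeq2 gave 39 for 13 in neutrophil, 731 for 1233 in macrophage, 632 for 1228 in osteoclast and 22 for 37 in T cells (treated model), 1764 for 2654 in fibroblast cells (interaction), 13 for 0 in endothelial cells (drug alone). DESeq2 lost the call of Irf8 (pooled, treated model, 0.41 for 0.42). The 80% rule gave 0 for 3 in dendritic and 25 for 202 in fibroblast cells (drug alone), 17 for 37 in T cells (treated model), 970 for 2654 in fibroblast cells (interaction). The 80% rule gained the call of interferon genes (fibroblast, model, 1.13 for 1.03). The 80% rule lost the call of interferon genes (fibroblast, drug alone, -0.0199 for 0.28). The 80% rule turned the direction of cell cycle genes (fibroblast, drug alone, -0.41 for -0.10). Keeping doublets gave 45 for 13 in neutrophil and 4 for 37 in T cells (treated model), 10 for 3 in dendritic cells (drug alone). Keeping doublets lost the call of Irf8 (pooled, treated model, 0.38 for 0.42) and Irf8 (pooled, interaction, 0.84 for 0.89). Keeping doublets gained the call of interferon genes (fibroblast, model, 1.40 for 1.03). Leiden 2.0 gave 34 for 13 in neutrophil cells (treated model). Leiden 2.0 turned the direction of cell cycle genes (neutrophil, model, -2.23 for 0.39) and cell cycle genes (osteoclast, treated model, 0.18 for -0.27). Leiden 2.0 gained the call of osteoclast differentiation genes (pooled, treated model, -0.37 for -0.29) and interferon genes (fibroblast, model, 1.18 for 1.03). Leiden 2.0 turned the osteoclast share difference, drug alone, from -0.0479 to 0.0168 points. Summing all cells moved interferon genes (osteoclast, treated model, 3.80 for 4.59) and matrix degradation genes (fibroblast, model, 1.00 for 1.84). Summing all cells turned the direction of antigen presentation genes (fibroblast, treated model, -0.30 for 0.32). The 100-UMI list minimum turned the direction of interferon genes (macrophage, drug alone, -0.77 for 0.40) and interferon genes (pooled, drug alone, -0.10 for 0.43). Leaving out TMM factors gave 4 for 13 in neutrophil cells (treated model). Totals without markers and top genes gained the call of interferon genes (fibroblast, model, 0.97 for 1.03). Putting fibroblast clusters back gained the call of interferon genes (fibroblast, model, 1.13 for 1.03). Neutrophil gene counts (treated model, 13) were 3 without KBxN 1 and KBxN 2, 4 without DAC_KBxN 3 and KBxN 3 and 24 without DAC_KBxN 2. Monocyte gene counts (treated model, 51) were 22 without KBxN 1 and 126 without DAC_KBxN 1. Macrophage gene counts (drug alone, 53) were 18 without Control 3, 27 without DAC 2, 139 without DAC 1 and 237 without Control 1. Dendritic gene counts (treated model, 113) were 29 without DAC_KBxN 1, 38 without KBxN 2, 41 without KBxN 3, 46 without DAC_KBxN 3, 60 without KBxN 1 and 108 without DAC_KBxN 2. Dendritic gene counts (drug alone, 3) were 0 without DAC 1 and Control 2, 6 without Control 3 and 11 without Control 1. T cell gene counts (treated model, 37) were 12 without DAC_KBxN 1, KBxN 2 or KBxN 3, 14 without DAC_KBxN 3, 15 without KBxN 1 and 20 without DAC_KBxN 2. Fibroblast gene counts (drug alone, 202) were 111 without DAC 2, 130 without Control 1 and 184 without Control 3. Endothelial gene counts (treated model, 58) were 23 without KBxN 3, 24 without DAC_KBxN 1, 30 without KBxN 2, 35 without DAC_KBxN 2 and 51 without DAC_KBxN 3. Endothelial gene counts (drug alone, 0) were 0 without DAC 1, 1 without DAC 2, 5 without DAC 3 and 13 without Control 3. Pooled Irf8 values (treated model, 0.42) were 0.33 without KBxN 3, 0.39 without DAC_KBxN 3, 0.44 without KBxN 1 and 0.51 without KBxN 2. Pooled Irf8 values (interaction, 0.89) were 0.51 without Control 3, 0.79 without DAC 1, 0.81 without KBxN 3, 0.87 without DAC_KBxN 3, 0.92 without KBxN 1, 0.93 without DAC_KBxN 2 and DAC_KBxN 1, 0.94 without DAC 2, 0.98 without DAC 3 and 1.07 without Control 2. Macrophage interferon gene medians (drug alone, 0.40) were 0.0989 without Control 3, 0.38 without DAC 2 and 0.70 without Control 1. Pooled interferon gene medians (drug alone, 0.43) were 0.14 without Control 3, 0.41 without DAC 2 and 0.57 without DAC 3. Pooled antigen presentation gene medians (drug alone, -0.54) were -0.83 without Control 1, -0.37 without Control 2, -0.33 without DAC 2 and -0.25 without Control 3. Fibroblast interferon gene medians (model, 1.03) were 0.92 without KBxN 2, 1.11 without Control 3 and 1.12 without KBxN 3. Fibroblast cytokine gene medians (drug alone, 0.0221) were -0.0300 without Control 3, 0.11 without DAC 1 and 0.12 without Control 2. Endothelial interferon gene medians (drug alone, 0.64) were 0.41 without DAC 2, 0.56 without Control 2 and 0.82 without DAC 1. Higher and lower calls without TMM factors were neutrophil 1146 and 621 (from 850 and 893, model), neutrophil 1 and 3 (from 5 and 8, treated model), monocyte 33 and 18 (from 43 and 8, treated model) and macrophage 18 and 39 (from 25 and 28, drug alone). Higher and lower calls without TMM factors were osteoclast 629 and 735 (from 769 and 459, treated model), T cell 20 and 9 (from 30 and 7, treated model), fibroblast 55 and 156 (from 95 and 107, drug alone) and endothelial 801 and 489 (from 600 and 623, model). Higher and lower calls with DESeq2 were neutrophil 11 and 28 (from 5 and 8, treated model), dendritic 0 and 3 (from 1 and 2, drug alone), T cell 22 and 0 (from 30 and 7, treated model) and endothelial 24 and 8 (from 18 and 3, interaction). Higher and lower calls with totals lacking markers and top genes were monocyte 37 and 15 (from 43 and 8, treated model), osteoclast 660 and 645 (from 769 and 459, treated model) and fibroblast 70 and 124 (from 95 and 107, drug alone). The median of all genes shifted without TMM factors by log2 0.20 in neutrophil (model) and 0.12 in endothelial (model).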

Other observations

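Neutrophil-like cells of KBxN joints had more of the interferon-stimulated genes Rsad2 (log2 2.39 ± 0.25, adjusted p = 1.2e-09), Rtp4 (1.31 ± 0.33, adjusted p = 0.00204) and Oasl2 (0.74 ± 0.21, adjusted p = 0.00440) than those of Control joints. Of 11 such genes 6 rose, 0 fell and 5 were not called (median 0.78, 8 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0374, upward, adjusted p = 0.303 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 1.31 ± 0.16 and the phosphofructokinase gene Pfkl by 1.60 ± 0.35, and the secondary granule gene Lcn2 fell by -2.35 ± 0.47 and Retnlg by -1.55 ± 0.19. In dendritic cell-like cells of KBxN joints Ciita, the regulator of class II genes, rose by 1.20 ± 0.24 and the immunoproteasome gene Psmb9 by 1.08 ± 0.19. The stress genes Dusp1 and Hspa1a fell there by -1.14 ± 0.13 and -1.90 ± 0.24.

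In macrophage-like cells the drug effect with arthritis lay below that without it for glycolysis and hypoxia and for inflammatory macrophage genes. Of 9 glycolysis and hypoxia genes 0 had a higher effect, 3 a lower effect and 6 were not called (median -0.69, 0 higher and 7 lower when adjusted over the list alone, camera adjusted p = 3.6e-10, downward, 0.0394 with an estimated correlation). Of 11 inflammatory macrophage genes 0 had a higher effect, 1 a lower effect and 10 were not called (median -0.97, 0 higher and 4 lower when adjusted over the list alone, camera adjusted p = 1.7e-08, downward, 0.0394 with an estimated correlation). It lay above for antigen presentation. Of these 13 genes 6 had a higher effect, 0 a lower effect and 7 were not called (median 1.09, 7 higher and 0 lower when adjusted over the list alone, camera adjusted p = 7.6e-15, upward, adjusted p = 0.0754 with an estimated correlation). Heat shock and chaperone genes in fibroblast-like cells had a lower drug effect with arthritis. Of the 7 members 0 had a higher effect, 6 a lower effect and 1 was not called (median -0.54, 0 higher and 6 lower when adjusted over the list alone, camera adjusted p = 1.2e-09, downward, 0.0282 with an estimated correlation).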
